A study of Mus musculus with 2 samples.

How the data were processed

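One chromatin immunoprecipitation sequencing (ChIP-seq) library, made with an antibody to KLF4, was analysed as a list of enriched regions (peaks). The series also has an input library, that is, sheared DNA sequenced without antibody, for which no processed values were used here. Per the labels, the cells were GFP-positive, CD4 and CD8 double-positive bone marrow cells sorted from mice with T cell acute lymphoblastic leukaemia (T-ALL) driven by NOTCH1, DNA was sheared and the ChIP libraries were sequenced on an Illumina instrument. The genotype of the ChIP library is not settled by its labels. The ChIP library is labelled as a Klf4 knockout and the input library as normal, while both carry the same strain name with floxed Klf4 and Vav-Cre, a recombinase expressed in blood cells. The libraries were therefore grouped by antibody only, and the list is called the KLF4 ChIP list without a genotype.

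Per the submitters' processing notes, reads were processed with BWA 0.6.1, a short-read aligner, and SICER 1.1 and MACS, both peak callers, are also named without a role. The same notes name the genome builds hg19 and mm9. Read filters, the threshold for calling a peak and whether the input library was subtracted are not given in the sources used here. Per the file headers, the authors deposited 2 tracks, one of summits and one of intervals. The score in the summit track is the authors' value for each peak. Its scale is named nowhere, it takes only whole numbers from 8 upwards, and it is called the peak height here. It was used to rank, filter and describe peaks within this list. For chromosome X, heights were also divided by 2, which takes the score as proportional to signal. The depth of the library is unknown, so no interval for sequencing depth can be given. Intervals printed for counts of peaks cover counting error only, and are too narrow where peaks lie in clusters.

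The other deposited columns are start and end positions in base pairs. Interval starts were converted to positions counted from 1, and summits were kept as written. Summits and intervals were joined by their order within each track, and 8148 of 8148 summits lay inside the interval of the same rank. Of the summits, 75.1% were multiples of 32 bp and another 18.9% lay 16 bp off that grid, so the signal behind the summits was binned and a summit is known only to about 32 bp.

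The chromosomes were those of the mouse. The last peak lay beyond the last gene of the GRCm38.p6 gene table on 7 of 21 chromosomes. That goes with another build. The comparison used last genes and not chromosome lengths, so on its own it does not settle the build. Positions are given as mm9, a build named in the submitters' notes. No mm9 genome or gene annotation was used here. Peaks were therefore described by position, and no gene was assigned to a peak. The tests planned on promoters, annotation classes, sequence motifs, fixed gene lists and peak height at promoters were not run for that reason. That includes lists for the JNK, NOTCH, Wnt and PI3K pathways, T-ALL regulators, T cell identity, cell cycle, apoptosis, the KLF and SP family, pluripotency, other blood lineages and other tissues.

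Peak density on a chromosome was the number of peaks divided by the span from its first to its last peak, with a 95% exact Poisson interval. Ratios of densities carry a 95% exact binomial (Clopper-Pearson) interval. The gap between neighbouring peaks ran from the end of one interval to the start of the next. The share of gaps of at most 10 kb was compared with 1000 placements of the same number of intervals at random, without overlap, within the span of each chromosome (two-sided permutation test). This null keeps neither gene density nor mappability. The smallest two-sided p it can give is 0.002. The densest windows of 500 kb were compared with 100 such placements. In simulated lists for this comparison, tested with 200 placements each, a list of 8103 randomly placed intervals gave a permutation p of 0.746, and a list of 8086 intervals with 10% of them planted near another gave 0.00995, the smallest p that 200 placements can give. Medians were compared by permutation with 100000 resamples, two-sided. With 1 library there are no replicates, and every p-value describes the placement or height of peaks in this list, not a difference between conditions.

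Peaks named in the text follow a rule set before the data were examined, the 10 tallest peaks of the list. The widest peaks, the densest windows, the longest gaps and the peaks at the end of chromosome X were chosen after their values were seen, as were the Fisher's exact tests of wide intervals and of peak heights on chromosome X. Alternatives set before the data were examined were only peaks at or above the median height of 15, merging of peaks within 1 kb, leaving out chromosome Y, and gap limits of 1 and 100 kb. Calculations used Python 3.11.15 with numpy, pandas and scipy 1.17.1.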

Results

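The series used an antibody to KLF4, a zinc finger transcription factor of the Krüppel-like family, to profile chromatin in mouse leukaemia cells. The cells were double-positive for CD4 and CD8, carried the GFP marker, and came from the bone marrow of mice with T-ALL driven by NOTCH1. The title of the series links loss of KLF4 to the Map2k7 and JNK kinase pathway. The data consisted of 1 list of 8148 peaks from 1 KLF4 ChIP library. There were no replicates, and no list from the input library or from a second genotype was analysed here. No comparison between conditions was therefore possible, and the comparisons made are between regions of the genome within this list. The ChIP library carries a knockout label, so whether its antibody target was present in the cells could not be told from the labels. If that label is right, the antibody had no intact target and the list would hold background, so the peaks, their heights and their clusters are described as regions listed for this antibody and are not shown to be KLF4 binding sites.

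The KLF4 ChIP peaks were mostly short intervals, and most heights lay near the lower end of their range. The median width was 1137 bp, with quartiles of 896 and 1509 bp, and the intervals covered 10.7 Mb, or 0.423% of the span between the first and last peaks of the chromosomes. The median height was 15, with quartiles of 13 and 19, and the lowest was 8. Taller peaks were wider across the list (Spearman rho = 0.53 across peaks, which are not independent replicates). Only 290 peaks (3.56%) reached a height of 30, and 29 reached 50.

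In height, 6 peaks stood apart from all others (positions are given as mm9). The tallest peak lay on chromosome 17 at 39979510 to 39985903 and had a height of 278 over 6394 bp. The next lay on chromosome 11 at 108872504 to 108873657, with a height of 180. A peak of only 457 bp on chromosome 3 at 5860487 to 5860943 had a height of 147. Chromosome 15 held a peak of height 129 at 74915832 to 74917601. A peak on chromosome 5 at 147072232 to 147073060 reached 115, and one on chromosome 19 at 61275151 to 61275932 reached 114. No other peak exceeded a height of 69. The other 4 of the 10 tallest peaks had heights of 69 (chromosome 9, 66358078 to 66363223), 60 (chromosome 19, 3767165 to 3769361), 59 (chromosome 3, 95732344 to 95734999) and 59 (chromosome 7, 80681890 to 80684466). Of the 10 tallest, 3 were narrower than the median peak. The sequence under these peaks was not examined, so whether repeated sequence contributes to the height of any of them, the peak of height 278 included, is not known.

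**Figure D1:**
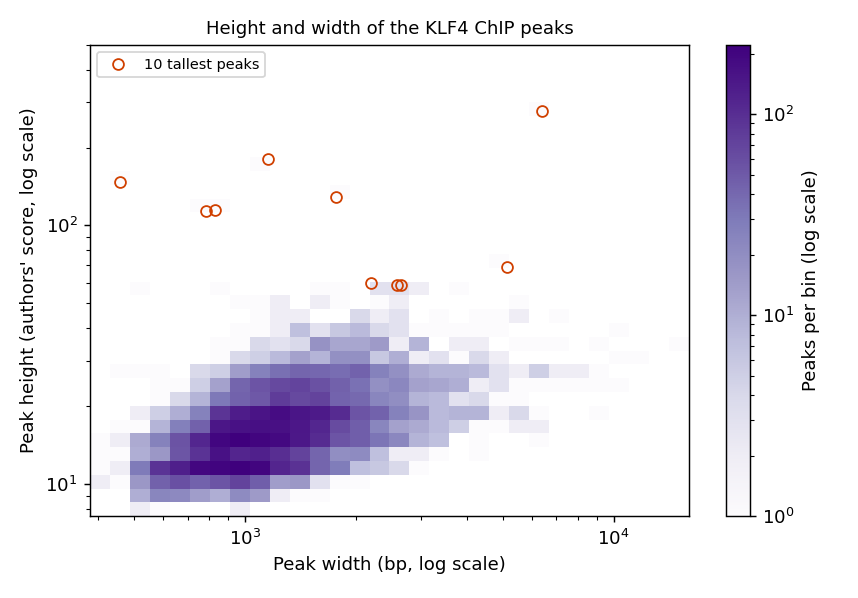
Width of each peak in bp (x axis, log scale) against its height, the authors' score (y axis, log scale), as the number of peaks per bin for the 8148 peaks of 1 library; circles mark the 10 tallest peaks. Most peaks form 1 cloud in which height increases with width, and 6 peaks with heights of 114 to 278 lie above it.

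The widest peak was not among the 10 tallest. Of the 8148 intervals, 46 were wider than 5 kb, with a median height of 26, and these included the peaks of height 278 and 69. The widest covered 15682 bp on chromosome 5 at 121124190 to 121139871, with a height of 33. Chromosome 11 held an interval of 12159 bp at 52086139 to 52098297 and one of 9922 bp at 52062616 to 52072537, both between 52062616 and 52098297. An interval of 10069 bp lay on chromosome 5 at 124564179 to 124574247. On chromosome 2, an interval of 9776 bp at 26311648 to 26321423 was followed after a gap of 78 bp by one of 8163 bp at 26321502 to 26329664, with heights of 38 and 26. Another peak lay within 1 kb of 32 of the 46 wide intervals (69.6%), against 1193 of the other 8102 (14.7%; Fisher's exact test, two-sided, p = 9.14e-17, unadjusted). This test and its limit of 5 kb were chosen after the values were seen, and it treats peaks as independent. The leukaemia was driven by NOTCH1, and whether reads from an introduced NOTCH1 sequence contribute to any of these wide intervals, those on chromosome 2 included, was not examined.

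Peaks were distributed unevenly over the chromosomes. Chromosome 11 held 820 peaks, which was 10.1% of the list (95% exact binomial interval 9.42 to 10.7%). Its density was 6.92 peaks per Mb of span, 2.16 times that of the other autosomes together (95% interval 2.003 to 2.317). Chromosome 19 followed with 5.17 per Mb (95% Poisson interval 4.599 to 5.786) and chromosome 17 with 4.89 (4.45 to 5.36). The lowest autosomal density was 2.20 per Mb on chromosome 14 (1.94 to 2.49), and chromosomes 3, 1 and 18 were close to it, at 2.27, 2.33 and 2.38 per Mb. Median heights on the 19 autosomes lay between 15 and 16 and median widths between 1058 and 1215 bp. The densest autosomes, chromosomes 11, 19 and 17, had the largest median widths (1196, 1215 and 1179 bp). Those of the sparsest, chromosomes 14, 3, 1 and 18, were 1085, 1135, 1162.5 and 1093 bp. No test of width against density was run.

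Chromosome X held 78 peaks, or 0.490 per Mb (0.387 to 0.611), below the interval of every autosome. Its density was 0.144 times the autosomal density of 3.39 per Mb (95% interval 0.114 to 0.180), and the ratio was 0.0933 (0.0624 to 0.134) among peaks at or above the median height of 15. The X peaks had a median height of 13 and a median width of 820 bp. A height of 20 was reached by 8 of the 78 X peaks (10.3%) and by 1936 of the 8069 autosomal peaks (24.0%; Fisher's exact test, two-sided, p = 0.00311, adjusted to 0.00932 over 3 tests of heights and distances). Chromosome Y held 1 peak, at 346577 to 347245, with a height of 12.

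**Figure D2:**
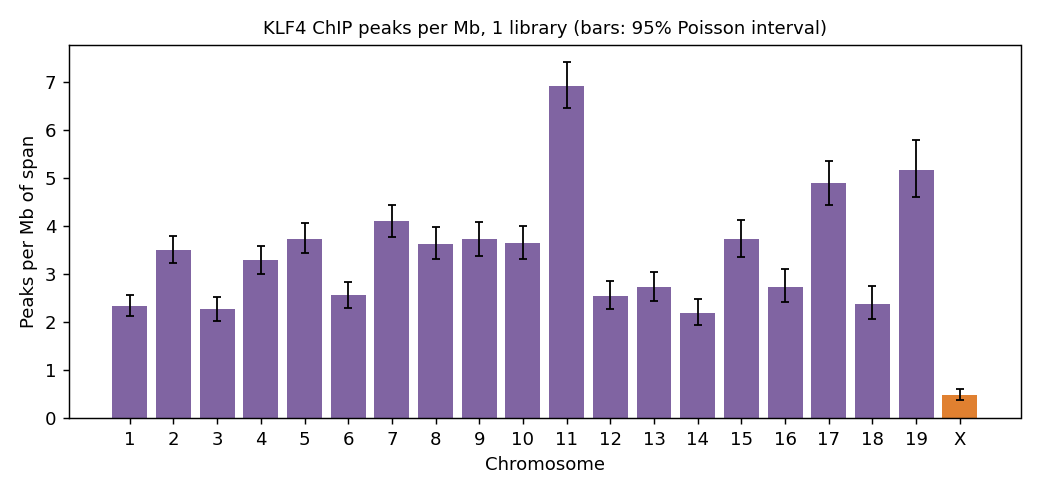
Peaks per Mb between the first and last peak (y axis) for each chromosome (x axis) in 1 library; error bars are 95% Poisson intervals for the count of peaks. Chromosome 11 reaches 6.92 per Mb and chromosome X 0.490 per Mb; chromosome Y, with 1 peak, has no span.

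Pooled over the chromosomes, neighbouring peaks lay closer together than random placement gave. Of 8127 pairs of neighbouring peaks, 1749 (21.5%) were separated by at most 10 kb. Random placement within the same spans gave 3.66% on average and at most 4.25% in 1000 draws (two-sided permutation p = 0.002, the smallest the draws can give). The excess was 5.87-fold over the random mean. The median gap was 52.7 kb. Some neighbours were nearly contiguous, and 219 pairs were separated by less than 100 bp.

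**Figure D3:**
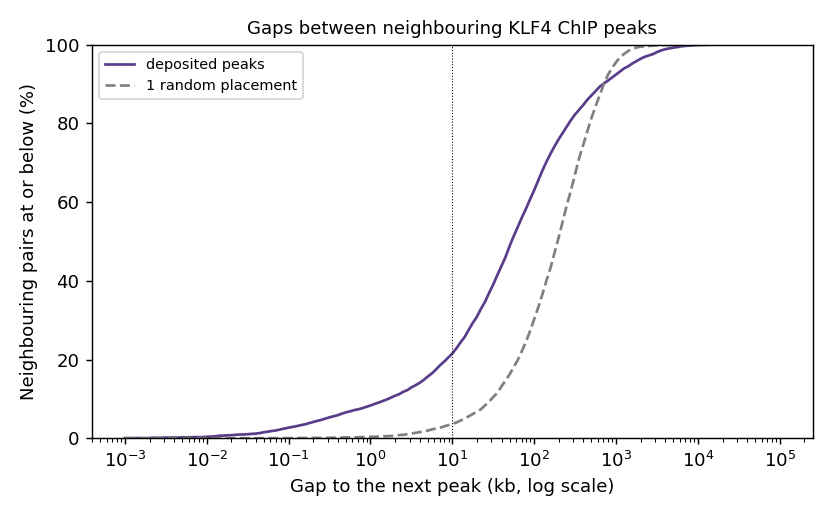
Cumulative percentage of neighbouring peak pairs (y axis) with a gap at or below the value on the x axis (kb, log scale), for the deposited peaks and for 1 random placement; the dotted line marks 10 kb. At 10 kb the deposited list reaches 21.5%, against a mean of 3.66% over 1000 random placements.

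A small share of the genome held a larger share of the peaks. Windows of 500 kb with 10 or more peaks numbered 148, or 2.91% of the windows, and held 2167 peaks (26.6%). Random placement gave at most 3 such windows in 100 draws. Peaks were counted as deposited, so nearly contiguous intervals count separately, and the window counts were not repeated after merging within 1 kb. The densest window, on chromosome 10 at 80500001 to 81000000, held 38 peaks, against at most 13 in any window of the random draws. It belonged to a 2 Mb stretch from 79 to 81 Mb that held 110 of the 451 peaks of chromosome 10 (24.4%), with a median height of 17. On chromosome 13 the window at 23500001 to 24000000 held 30 peaks, with a median width of 918 bp. Chromosome 8 held 29 peaks at 73000001 to 73500000. Chromosome 5 held 28 peaks at 124500001 to 125000000, the window with the 10069 bp interval. Chromosome 17 held 26 peaks at 35000001 to 35500000, and the first megabases of chromosome 19 had the window at 4000001 to 4500000, also with 26.

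Long stretches held no peak. Of the 500 kb windows, 55.8% were empty, against 24.3% on average under random placement and at most 25.5%. The longest autosomal gaps were 13.2 Mb on chromosome 15 (12755257 to 25913623), 12.95 Mb on chromosome 14 (105577052 to 118531795) and 11.6 Mb on chromosome 14 (87816872 to 99444822). The longest autosomal gap in the random placements was 5.19 Mb. Chromosome X had a gap of 27.9 Mb (103222918 to 131119906).

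**Figure D4:**
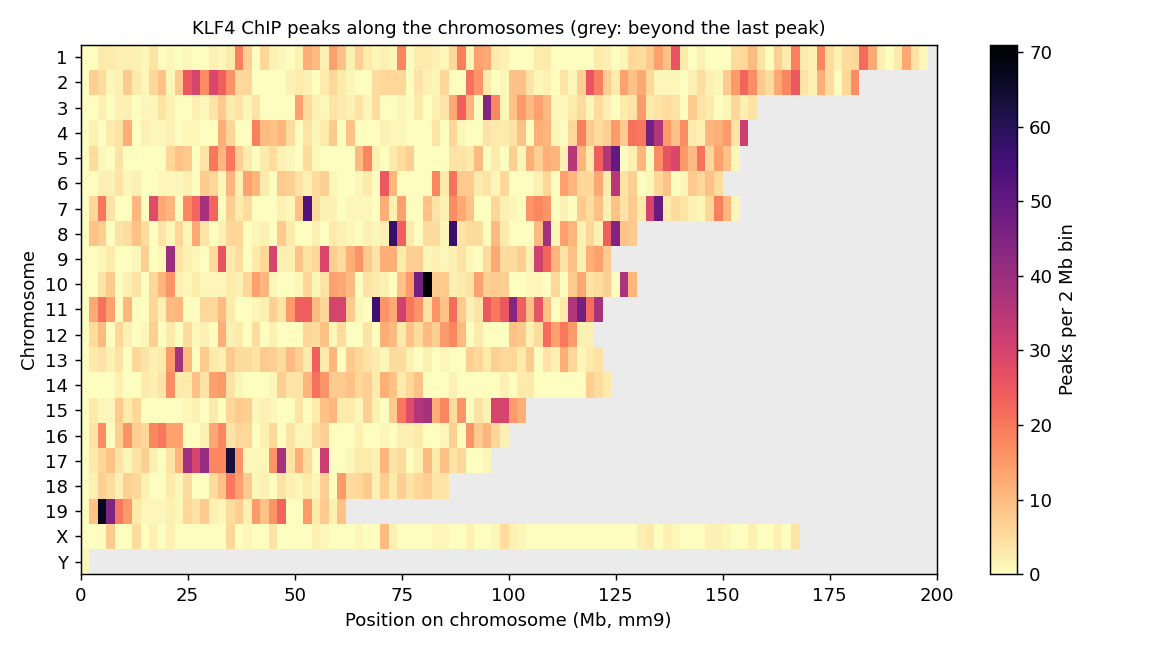
Number of peaks in bins of 2 Mb (colour) along each chromosome (rows), by mm9 position in Mb (x axis), in 1 library; grey lies beyond the last peak of a chromosome. Bins with up to 71 peaks lie beside long stretches with few or none, and no bin of chromosome X holds more than 10.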

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

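The list had 4665 peaks when only those at or above the median height of 15 were kept, 7472 when peaks within 1 kb were merged and 8147 without chromosome Y. The share of close neighbours stayed above random placement in every alternative run (two-sided permutation p = 0.002 in each). It was 8.32% within 1 kb against 0.374% at random, 63.0% within 100 kb against 30.6%, and 12.4% within 10 kb among peaks at or above the median height against 2.15%. Merging peaks within 1 kb first, an alternative chosen after seeing the data like all those that follow, gave 14.4% against 3.35%, and leaving out 9 tall narrow peaks gave 21.5% against 3.67%. The ratio of X to autosomal density was 0.0933 among peaks at or above the median height (95% interval 0.0624 to 0.134), 0.153 after merging and 0.137 without the 4 last X peaks. The ratio of chromosome 11 to the other autosomes was 2.09 among peaks at or above the median height and 2.11 after merging. The alternatives planned for promoters, annotation classes, motifs, gene lists and peak heights at promoters were not run, because no mm9 genome or annotation was used here. No replicate could be left out. No paired analysis was possible because each group has 1 library and only 1 was analysed. The unknown sequencing depth and calling threshold limit what the absence of a peak means, since a site below the threshold is not in the list.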

Other observations

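The tests of peak heights on chromosome X and the values for heights divided by 2 were chosen after the X values were seen, and the report's test of neighbours of wide intervals after the widths were seen. The tests of split regions, of missed X peaks and of the distance between tall peaks were written down before their results. The 4 last X peaks in the list lay within 166434673 to 166445211 and had heights of 55, 53, 17 and 26. No other X peak exceeded 27. The distal end of the mouse X chromosome is also where the pseudoautosomal region, shared with the Y chromosome, lies. Whether these 4 peaks fall inside it was not tested, since no mm9 annotation was used here.

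The scarcity of peaks on chromosome X has a candidate explanation in lower signal there, as cells with a single X would give. The difference of median heights, X minus autosomes, was -2.0 (13 against 15; permutation p = 0.0447, or 0.0671 after Benjamini-Hochberg adjustment over 3 tests), and the share of X peaks of height 20 or more was lower too (adjusted Fisher's exact p = 0.00932), which goes with lower signal but does not say what lowered it. If heights of autosomal peaks were divided by 2, 49.0% of them would stay at or above 8, the lowest height in the list. At or above 10, 24.0% would stay. Both shares are more than the X density ratio of 0.144 (upper bound 0.180). A single copy with a fixed limit at those heights would then leave more X peaks than were listed, if height is proportional to signal. Whether it is proportional is not known, since the scale of the heights is named nowhere. At or above 12, a limit above the 10th percentile of the list (11), 11.3% of all autosomal peaks would stay. That total includes peaks under 12, which such a limit would itself remove, so this share cannot be set against the ratio. No other limit was tried. Among peaks at or above the 90th percentile of height the ratio was 0.0821 (5 X peaks, 95% interval 0.0266 to 0.192). These 5 include the peaks of height 55, 53 and 26 at the end of X, and the ratio was not computed without them. The ratio of 0.0821 was below a bound of 0.5 set beforehand to exclude missed peaks as the whole explanation. That bound holds only where X heights equal autosomal ones, since heights divided by 2 would give 0.0319, a value inside the interval of the ratio. Missed peaks and a lower number of enriched regions on X therefore cannot be told apart with the threshold unknown, and gene content and mappability of X were not tested.

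Close neighbours among the peaks could come from a caller that splits broad regions into adjacent intervals. After merging intervals within 1 kb, 45.3% of neighbouring regions still had a gap of 10 to 100 kb, against 25.1% at random (two-sided permutation p = 0.002, the smallest the draws can give). Splitting into pieces at most 1 kb apart would not give that excess. The range of 10 to 100 kb holds none of the pairs within 10 kb, so the test does not say what part of those pairs came from splitting. After the same merging 14.4% of neighbours were within 10 kb, against 3.35% at random, and pieces 1 to 10 kb apart would remain among them. Splitting as a source of close pairs stays open, since 219 pairs were less than 100 bp apart. Uneven gene density and mappability were not tested, and no biological explanation was tested.

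The tallest intervals as a set followed the general relation of height and width, but they include narrow ones. Of the 79 peaks above the 99th percentile of height (38), 9 were narrower than the median peak, against 39.5 if height and width were unrelated. Among the 9 were the peaks of height 147 on chromosome 3, 115 on chromosome 5 and 114 on chromosome 19. Not all of the 9 were isolated, since those of height 53 on chromosome X and 50 on chromosome 4 lay 374 and 144 bp from another peak. A candidate explanation is stacks of reads at isolated sites, as repeated sequence collapsed in the assembly would give. The tall narrow peaks lay a median of 38.7 kb from their nearest other peak and the tall wide ones 11.9 kb (difference 0.51 on the log10 scale, permutation p = 0.258, also after adjustment over the 3 tests), so with 9 peaks the test did not decide. The sequence at these sites was not examined, and no biological explanation was tested.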
